A study of Mus musculus with 14 samples.

How the data were processed

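Per the labels, neutrophils were sorted from the blood of male C57BL/6 mice aged 7 to 10 weeks by staining for Ly6G after lysis of red cells, their RNA was amplified with a kit for small inputs, and 14 libraries were sequenced. The labels place wild-type samples at zeitgeber time (ZT) 5 and 13, clock times 12 and 20 h, and all mutants at ZT5. The notes that accompany the series name CASAVA 1.8.2, cutadapt, RSEM 1.2.3 and the mouse genome GRCm38; the normalization is not given in the sources used here. The authors deposited 1 table of normalized signal values per gene and library, for 11288 genes. Each column was found to be a whole number of reads times 1 constant (100% of values, tolerance 1e-06 reads, 1 read worth 0.127 to 0.244), so reads were recovered by division. Gm42418 alone held 5.76% to 12.0% of a column. Symbols and coordinates were found for 11188 identifiers, and 100 stayed without.

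Groups were compared with limma 3.58.1 in R 4.3.3, by a linear model with an intensity trend on log2(value + 1), with all 14 libraries and 5 groups in 1 fit. Genes with a mean value of at least 1 were tested, 11255 in number, and 33 were below it. This model was the one foreseen for a table that does not hold counts. Every adjusted p for a gene is a limma moderated t-test p adjusted by the Benjamini-Hochberg method over all genes tested, called at 0.05. An adjusted p over the list alone uses the same test over the members of that list. Comparisons were WT ZT13 with WT ZT5, each group labelled as mutant with WT ZT5, and the Cxcr4 mutants with the libraries labelled Cxcr2-deficient. For these group sizes, simulated changes of 1 log2 unit were recovered in 8% to 24% of 100 genes and changes of 2 in 51% to 65%, with 5 to 7 false calls, so many real changes of that size would be missed.

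Gene lists, 24 with 509 members of which 432 were tested, were chosen before the data were examined, as were the comparisons, the tests, the rule for named genes and most alternatives. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. The rule for named genes took, per comparison, the 10 genes with the largest absolute log2 fold change in each direction among those called, with a mean log2 value of at least 3 and groups that did not overlap, leaving out predicted genes and pseudogenes. Where a direction had fewer than 5, it was filled to 5 by smallest p, with those said not to pass. Arntl, Cxcr2 and Cxcr4 were always named, and up to 4 members of smallest p per list described. Some genes that the rule took are not reported here, although the counts include them.

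Agreement between comparisons was set against 100 simulated data sets without group differences. In these, the residuals of all 14 libraries were shuffled over the groups, so a control was shared but its own values were not kept. Scores of the groups labelled as mutant were compared by exact permutation. Genes within 20 Mb of each targeted gene were counted by Fisher's exact test, a test chosen after the result was seen. For a gene at 0 in a group, a floor of 3 reads per library was used. Floors cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

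The alternatives were a pseudocount of 0.1, no filter, a stricter filter, quantile normalization, DESeq2 size factors, array weights, a fold threshold, a fit of only the groups compared, a replicate block, and each library left out in turn, together with DESeq2 1.42.0, edgeR 4.0.16 in 2 planned forms and limma-voom on recovered reads. Further ones were chosen after seeing the data: edgeR with TMM scaling, the mean level of B cell markers as a covariate, a score without marker genes of other cells, and a fit without WT ZT5 replicate 5 as a case of its own. Isoforms, splicing and reads within a deleted segment were not analysed here.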

Results

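Neutrophils were sorted from mouse blood by Ly6G staining, and their polyadenylated RNA was sequenced in 14 libraries. The libraries fell into 5 groups. Wild-type mice gave 3 libraries at zeitgeber time (ZT, hours after lights on) 5 and 3 at ZT13. Mice carrying floxed alleles and a Cre recombinase driven by the neutrophil promoter Mrp8 were all sampled at ZT5, with 3 libraries for Bmal1 (the clock gene Arntl), 2 for the chemokine receptor Cxcr2 and 3 for the chemokine receptor Cxcr4. The recovered reads per library ranged from 4802511 to 6678645 in wild type at ZT5, 4082276 to 5454088 in wild type at ZT13, 5426845 to 6449119 in the libraries labelled Bmal1-deficient, 4504679 to 4712667 in the Cxcr2 group and 4613982 to 5594088 in the Cxcr4 mutants. Values are the deposited normalized read counts, and errors are SD over the libraries of a group (n = 3, except n = 2 for Cxcr2). The labels do not say whether replicates came from separate animals, so each p-value measures the spread between these samples. The same WT ZT5 libraries served as control for 4 comparisons. All groups labelled as mutant share the Cre, so its effect cannot be told apart from that of each deletion in a comparison with WT. Genes named by the rule fixed before the data were examined had groups that did not overlap, and list members beyond that rule were named after their values were seen. Gene list tests that assume a small fixed correlation between genes also passed for up to 13 lists when these samples were split in other ways, so each list is given with its result under an estimated correlation, and only lists that passed both are said to have moved.

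The targeted genes were examined first, to ask whether each mutant group could be recognised by its own transcript. Cxcr4 (ENSMUSG00000045382, chromosome 1, 128588199 to 128592293, GRCm38) fell from 435 ± 149 in WT ZT5 to 19.1 ± 6.56 in the Cxcr4 mutants, 4.38% of the control level. This was a log2 fold change of -4.43 (SE 0.26, limma adjusted p = 2.02e-11), and Cxcr4 was at 516 ± 130 in WT ZT13, 531 ± 49.4 in the libraries labelled Bmal1-deficient and 396 ± 37.4 in the Cxcr2 group. Cxcr2 (ENSMUSG00000026180, chromosome 1, 74153989 to 74161246) was abundant everywhere: 1757 ± 449 in WT ZT5, 2258 ± 163 in WT ZT13, 2052 ± 109 in the libraries labelled Bmal1-deficient and 1873 ± 247 in the Cxcr4 mutants. In the libraries labelled Cxcr2-deficient it was at 1354 and 1439, 79.5% of WT ZT5 (log2 fold change -0.30, SE 0.20, limma adjusted p = 0.542). With quantile normalization that change became -0.66 and passed the threshold (adjusted p = 0.0463). Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126) was low, with 100, 25 and 13 reads in the WT ZT5 libraries and 0 to 26 in the other libraries. Its values were 12.7, 5.28 and 2.68 in WT ZT5, 0, 5.07 and 0.731 in WT ZT13, and 4.37, 0 and 0 in the libraries labelled Bmal1-deficient. The change of Arntl in the libraries labelled Bmal1-deficient, -1.96 (SE 0.98), did not pass (limma adjusted p = 0.386). Counts over a whole gene retain reads from outside a deleted segment, and the labels do not say which part was removed. The values therefore left the Cxcr2 and Bmal1 labels unchecked, and these groups are called here the libraries labelled Cxcr2-deficient and Bmal1-deficient.

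**Figure D1:**
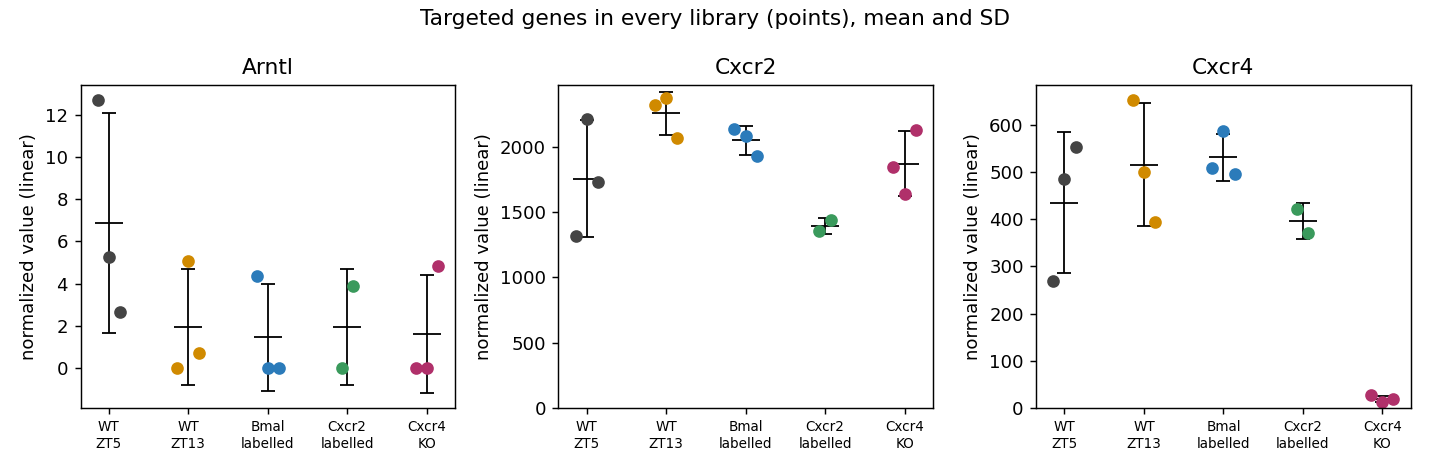
Normalized value (linear axis) of Arntl, Cxcr2 and Cxcr4 in each library (points) of the 5 groups, with mean and SD (bars). Cxcr4 lay at 19.1 ± 6.56 in its own mutants against 435 ± 149 in WT ZT5, whereas Cxcr2 lay at 1396 ± 60.2 in the libraries labelled Cxcr2-deficient.

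The comparison of WT ZT13 with WT ZT5 asked which transcripts of circulating neutrophils differ between evening and midday. The glucocorticoid-induced genes Fkbp5 and Il1r2 were higher at ZT13. Fkbp5, the co-chaperone of the glucocorticoid receptor, was at 176 ± 81.9 against 35.9 ± 11.4 (log2 fold change 2.18, SE 0.34, adjusted p = 0.00381). The decoy interleukin-1 receptor Il1r2 rose with it, from 121 ± 29.2 to 334 ± 7.02 (1.48, SE 0.21, adjusted p = 0.00171). The largest rise was that of Crispld2, a secreted protein that binds lipopolysaccharide, from 44.3 ± 29.0 to 314 ± 143 (2.87, SE 0.36, adjusted p = 0.000241). The phosphatase Ptp4a1 rose by 1.05 (adjusted p = 0.0293) and the Src-like adaptor Sla by 0.98 (adjusted p = 0.0453). In the other direction, Cd74, the invariant chain of antigen presentation, fell from 450 ± 394 to 67.3 ± 49.9 (-2.76, adjusted p = 0.0453), and Spn, the sialomucin CD43, from 178 ± 64.2 to a mean of 55.3 (-1.64, SE 0.30, adjusted p = 0.0250). The mitochondrial transcript mt-Nd1 fell from 211 ± 214 to 19.8 ± 10.0 (SE 0.53 on the log2 scale, adjusted p = 0.0181). The small nuclear RNA Rn7sk was at 234 ± 151 in WT ZT5 and at 0 in all ZT13 libraries, at least 371-fold lower against a floor of 3 reads per library (adjusted p = 0.0237). Its mean log2 value over all 14 libraries was 5.08. The libraries were made from polyadenylated RNA, and whether Rn7sk reflects the cells or the library preparation was not tested. H2-Eb1, at 34.4 ± 15.5 against 221 ± 201, had the next smallest p among the falling genes and did not pass (adjusted p = 0.0660). These 9 genes, 5 higher and 4 lower, were all that passed among 11255 tested, and 1193 genes had an unadjusted p under 0.05 where 563 would be given by chance. All 9 had groups that did not overlap, as did 1859 of all genes, a separation that 10% of genes show by chance with 3 libraries against 3.

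Among the fixed gene lists, none passed with an estimated correlation at ZT13. All 16 measured B cell markers were lower at ZT13 (median log2 fold change -2.60), of which 1 fell over all genes tested and 16 fell adjusted over the list alone (list test adjusted p = 3.58e-17; adjusted p = 0.208 with an estimated correlation). Monocyte and macrophage markers had a median of -1.04, with 0 of 17 called over all genes and 8 falling adjusted over the list alone (adjusted p = 4.89e-06; adjusted p = 0.208 with an estimated correlation). Ctss, for example, was at 132 ± 34.2 against 359 ± 152 (adjusted p = 0.0978). Interferon-stimulated genes had a median of 0.54, with 0 of 27 called and 8 rising adjusted over the list alone, among them Oas3, Rsad2 and Cmpk2 (adjusted p = 3.81e-08; adjusted p = 0.306 with an estimated correlation). Of 14 glucocorticoid genes, Fkbp5 and Il1r2 rose by both adjustments, over all genes and adjusted over the list alone (median 0.33, adjusted p = 0.000220; adjusted p = 0.211 with an estimated correlation). Erythroid genes (18 measured, median 0.56) and neutrophil identity genes (25 measured, median 0.29) had no member called, with 0 and 5 rising adjusted over the list alone (adjusted p = 4.89e-06 for each; adjusted p = 0.306 for each with an estimated correlation). Gelatinase granule, phagocytosis, homing receptor, motility and glycolysis genes had medians of 0.36, 0.29, 0.22, 0.15 and 0.17, no member called over all genes, and 2, 3, 3, 0 and 1 members rising adjusted over the list alone, with 1 homing receptor falling. Their list tests passed (adjusted p from 0.000220 to 0.0385) and were lost with an estimated correlation (adjusted p from 0.306 to 0.521). Motility genes moved the other way under quantile normalization. None of the 13 clock genes measured was called, by either adjustment (list adjusted p = 0.917). Tef, a clock output factor, was at 2.42 against 10.2 (adjusted p = 0.430) and Per1 at 251 against 187 (adjusted p = 0.552); Nr1d1 was not analysed here. The remaining 12 lists did not pass (adjusted p from 0.0627 to 0.982).

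The count of 9 genes changed with single libraries: it was 4 without WT ZT5 replicate 5, 102 without WT ZT5 replicate 8, 2 without WT ZT13 replicate 2 and 2 without WT ZT13 replicate 9, and edgeR called 3. These were all higher with TMM or RLE scaling and 2 higher with 1 lower in the robust form. Crispld2 and Il1r2 kept their calls whichever library was left out (highest adjusted p 0.0247), but all 9 lost theirs with the mean level of B cell markers as a covariate (Crispld2 0.538, Il1r2 0.822) and Crispld2 also with robust edgeR (0.105). Each of the other 7 lost its call without at least 1 library, Fkbp5 without either of WT ZT13 replicates 2 and 9 (highest adjusted p per gene from 0.114 to 0.334).

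**Figure D2:**
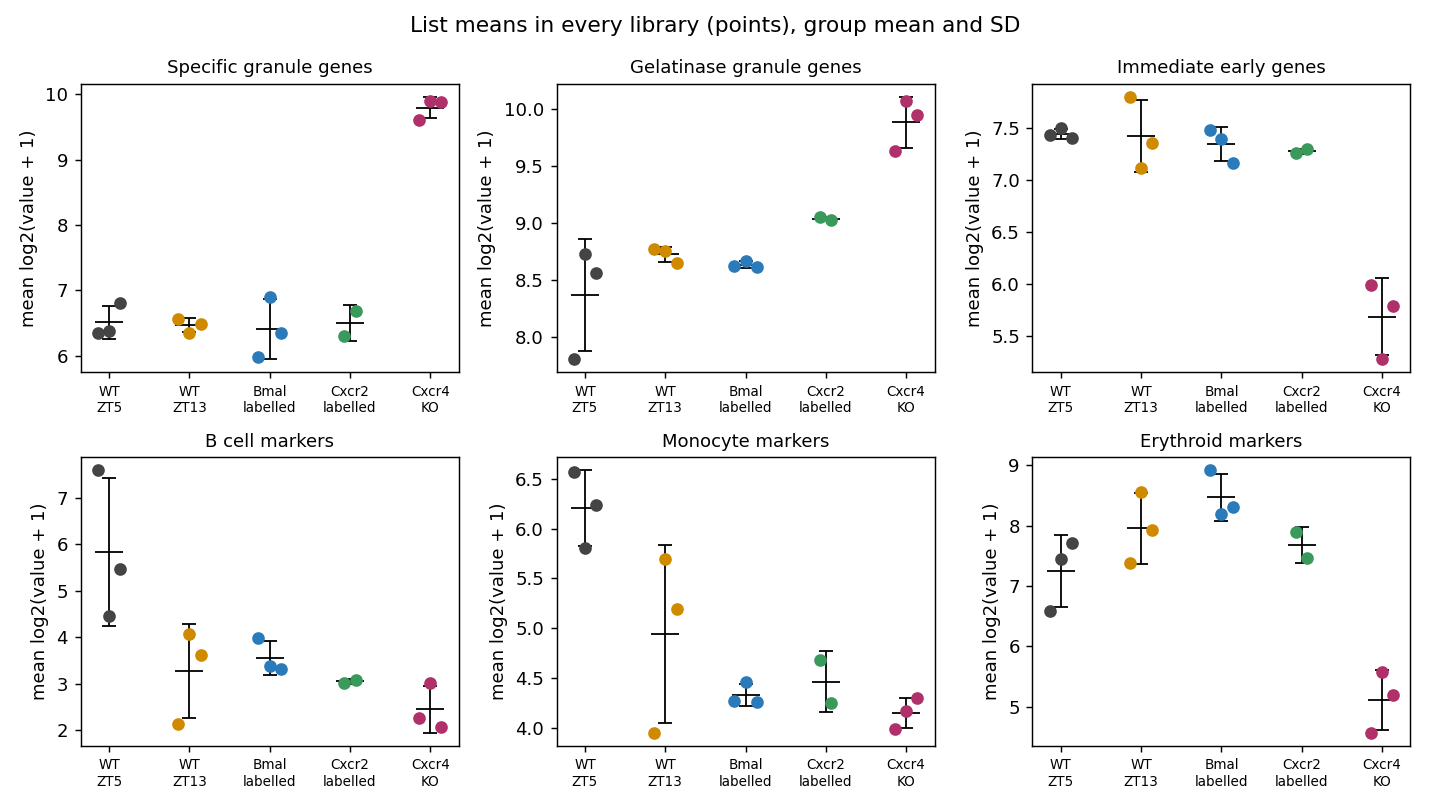
Mean log2(value + 1) of 6 gene lists in each library (points) of the 5 groups, with mean and SD (bars). Specific granule genes lay at 9.80 ± 0.17 in the Cxcr4 mutants against 6.51 ± 0.25 in WT ZT5, and B cell markers at 5.83 ± 1.60 in WT ZT5 against 3.27 ± 1.01 in WT ZT13.

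The comparison of the libraries labelled Bmal1-deficient with WT ZT5 asked what loss of the clock gene in neutrophils changes at midday. Some red cell transcripts were higher in these libraries: Hbb-bt, a beta globin, stood at 13934 ± 1403 against 3547 ± 1213 (log2 fold change 2.04, SE 0.32, adjusted p = 0.00196), and Bpgm rose by 1.41 (adjusted p = 0.0473). The integrin Itgax rose from 65.2 ± 15.2 to 251 ± 65.8 (1.92, SE 0.29, adjusted p = 0.00154), and the interferon-stimulated genes Rsad2 and Cmpk2 rose by 1.48 (SE 0.24, adjusted p = 0.00245) and 1.44 (adjusted p = 0.00811). Several monocyte genes were lower. The chemokine receptor Ccr2 fell from 168 ± 69.4 to 9.08 ± 7.59 (-4.46, SE 0.71, adjusted p = 0.00245) and Cx3cr1 from 49.2 ± 9.25 to 1.21 ± 1.25 (-4.64, adjusted p = 0.00811). Ahnak, a large scaffold protein, fell from 697 ± 365 to 68.1 ± 14.5 (-3.22, SE 0.32, adjusted p = 1.27e-06). Specc1, Cd300c2, Ninj1 and P2ry2, the nucleotide receptor, rose by 1.59, 1.46, 1.45 and 1.31. Pgap1, Lrp1, Ralgps2, Ablim1, Ccdc50, Ipo8 and Grk3 fell, with changes of -3.71, -3.61, -3.44, -3.43, -3.43, -3.25 and -3.21 (adjusted p from 0.0144 to 0.0473). In total 46 genes were higher and 69 lower, and 1517 had an unadjusted p under 0.05. Of the 115, 109 had groups that did not overlap (2015 of all genes, 10% by chance). The balance of directions turned with limma-voom (77 higher, 49 lower), robust edgeR (22 and 17) and without WT ZT5 replicate 9 (57 and 38), WT ZT5 replicate 5 (14 and 9) or Bmal1 replicate 3 (15 and 13).

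By list, 18 erythroid genes had a median of 1.25, with 3 rising over all genes, Hbb-bt and Bpgm among them, and 11 rising adjusted over the list alone (list adjusted p = 2.23e-14; adjusted p = 0.174 with an estimated correlation). Hbb-bt can share reads with its neighbouring globin genes, so its own level is uncertain. Neutrophil identity genes (25 measured) had a median of 0.55, with 2 rising over all genes and 13 adjusted over the list alone (adjusted p = 2.49e-12; adjusted p = 0.174 with an estimated correlation). S100a8 rose from 1458 ± 453 to 3077 ± 252 (1.12, adjusted p = 0.0147) and Msrb1 from 502 ± 145 to 939 ± 64.1 (0.94, adjusted p = 0.0159). Of 7 NADPH oxidase subunits, Ncf1 (0.89, adjusted p = 0.0159) and Ncf4 (1.05, adjusted p = 0.0185) rose while Cybb fell from 457 ± 131 to 199 ± 24.4 (-1.16, adjusted p = 0.0182); 4 rose and 1 fell adjusted over the list alone (list adjusted p = 0.000588; adjusted p = 0.174 with an estimated correlation). Of 17 monocyte markers, Ccr2, Cx3cr1, Fn1 and Ace fell and 10 fell adjusted over the list alone (median -2.29, adjusted p = 4.60e-09; adjusted p = 0.130 with an estimated correlation). Of 16 B cell markers, Cd74 and H2-Eb1 fell and 13 fell adjusted over the list alone (median -2.18, adjusted p = 1.79e-11; adjusted p = 0.194 with an estimated correlation). Homing receptors had Itgax, Jaml and Cd24a rising, and 5 rising and 1 falling adjusted over the list alone (median 0.22). Interferon genes had Rsad2 and Cmpk2 rising, and 7 adjusted over the list alone (median 0.34). Motility genes had only Tmsb4x rising by either adjustment (7958 ± 540 against 3879 ± 625, median 0.32). The tests of these 3 lists passed (adjusted p from 5.31e-08 to 0.000964) and were lost with an estimated correlation (adjusted p from 0.362 to 0.418).

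Gelatinase granule and glycolysis genes had no member called over all genes, and 4 rising with 1 falling, and 0, adjusted over the list alone (medians 0.36 and 0.23, list adjusted p = 0.00904 for each; adjusted p = 0.427 and 0.418 with an estimated correlation). Phagocytic receptors differed in sign between median (0.15) and mean (-0.11), with Tyrobp and Fcgr3 rising, and 3 rising and 3 falling adjusted over the list alone (adjusted p = 0.0405; adjusted p = 0.431 with an estimated correlation). The direction turned under quantile normalization. No clock gene of 13 was called by either adjustment (list adjusted p = 0.617): Clock was at 6.83 against 20.6 (adjusted p = 0.240) and Cry1 at 49.0 against 27.9 (adjusted p = 0.387). The immediate early factor Klf4 fell from 55.9 ± 27.9 to 8.18 ± 2.91 (adjusted p = 0.0335), Il1rn rose by 1.21 (adjusted p = 0.00774) and Pmaip1 by 1.11 (adjusted p = 0.0473), within lists that did not pass. Those 13 lists had adjusted p from 0.103 to 0.792.

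Of the 115 called genes, 11 lay within 20 Mb of Arntl on chromosome 7 (5 higher, 6 lower), against 2.82 given by the share of tested genes there (Fisher's exact test, 2-sided p = 0.000119). Outside that window the chromosome held 5 calls against 5.55. The strongest was Gm1966, annotated as an unprocessed pseudogene, at 30.9 against 458 (-3.87, adjusted p = 1.21e-11). Gdpd3 was at 179 against 1.02 (6.62, adjusted p = 0.000213), and Trim30d, Trim12a and Trim30b changed by -4.95, -2.84 and -1.44. Itgax, Hbb-bt, P2ry2 and Spn were also in the window. Spn was at 58.6 against 178 in WT ZT5, but it was also low in WT ZT13 (55.3). Hbb-bt is 1 of 18 erythroid genes that all had positive changes. The calls of Spn and Hbb-bt therefore need not come from their position. Gm1966 and the Trim genes have close paralogs nearby that can share their reads, so their single values are uncertain; these genes were chosen after their values were seen. The matching windows held 3 calls against 1.45 around Cxcr2 (Fisher's exact p = 0.178) and 12 against 8.72 around Cxcr4 (Fisher's exact p = 0.283).

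**Figure D3:**
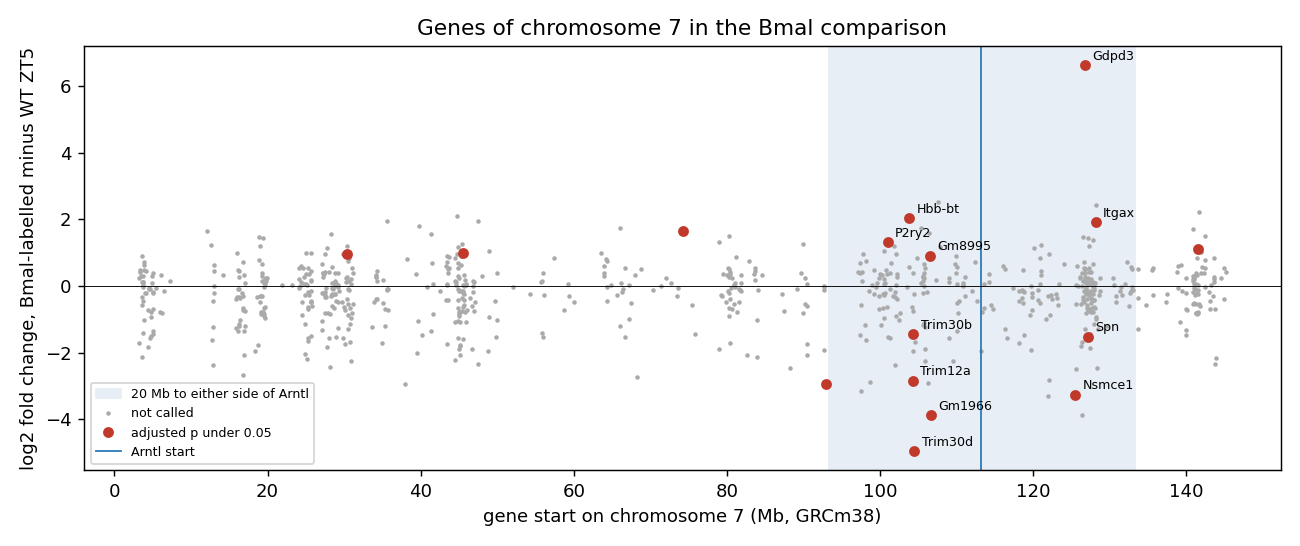
Log2 fold change of the libraries labelled Bmal1-deficient minus WT ZT5 against gene start (Mb, GRCm38) on chromosome 7, one point per tested gene, called genes in red and the 20 Mb window on each side of Arntl shaded. The window held 11 called genes, from Trim30d at -4.95 to Gdpd3 at 6.62.

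The 115 calls became 23 without WT ZT5 replicate 5, 190 without WT ZT5 replicate 8, and 68, 28 and 26 without Bmal1 replicates 2, 3 and 4. With edgeR 36 were called, and with DESeq2 264. Hbb-bt, Itgax, Specc1, Rsad2, Ccr2 and Ahnak kept their calls whichever library was left out (highest adjusted p 0.0430). Of these, Hbb-bt and Ccr2 lost theirs with robust edgeR (0.150 and 0.124). With the B cell covariate, which overlaps with this contrast too, 19 of the 20, all but Ahnak, lost theirs. The other 14 of the genes taken by the rule lost theirs without at least 1 library (highest adjusted p per gene from 0.0506 to 0.425, without WT ZT5 replicate 5 for all of them but Cmpk2, which lost it without Bmal1 replicate 4).

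The comparison of the libraries labelled Cxcr2-deficient with WT ZT5 asked what loss of this chemokine receptor, which promotes release from the bone marrow, changes in blood neutrophils. Several feedback genes of NF-kB signalling were higher: the inhibitor Nfkbia rose from 177 ± 99.3 to 530 ± 72.3 (log2 fold change 1.71, SE 0.33, adjusted p = 0.0126), Nfkbiz from 326 ± 42.7 to 770 ± 10.8 (1.25, SE 0.22, adjusted p = 0.00523) and the interleukin-1 antagonist Il1rn from 144 ± 51.5 to 364 ± 64.9 (1.38, SE 0.24, adjusted p = 0.00523). The calprotectin subunit S100a8 rose by 1.25 (adjusted p = 0.0193), S100a6 by 1.41 (adjusted p = 0.00472) and the chemokine Ccl6 by 1.16 (adjusted p = 0.00523). Xkrx had the largest rise, from 110 ± 80.3 to 797 ± 461 (2.95, SE 0.46, adjusted p = 0.00374), with Ctse and Ap1s3 at 1.99 and 1.47. The immediate early factor Egr1 fell from 918 ± 360 to 69.6 ± 23.7 (-3.68, SE 0.58, adjusted p = 0.00374). The monocyte genes Ccr2 (-4.96, adjusted p = 0.00374) and Fn1 (-3.86, adjusted p = 0.00523) fell, as did H2-Eb1 (-3.35, adjusted p = 0.00374). Slc12a2, Rassf4, Ttbk2, Itpr1 and Lrp1 fell, with changes of -5.34, -3.75, -3.64, -3.55 and -3.51 (adjusted p from 0.00538 to 0.0386). In total 24 genes were higher and 51 lower, and 1519 had an unadjusted p under 0.05. All 75 had groups that did not overlap, as did 3422 of all genes, where 20% do so by chance with 3 libraries against 2. The balance of directions turned with limma-voom (36 higher, 4 lower), robust edgeR (9 and 3), edgeR with TMM (9 and 8) and without WT ZT5 replicate 9 (30 and 19) or WT ZT5 replicate 5 (12 and 11).

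Of 27 NF-kB genes, Nfkbia, Nfkbiz and Il1rn rose and 5 rose adjusted over the list alone (median 0.51, list adjusted p = 1.98e-05; adjusted p = 0.109 with an estimated correlation). Tnfaip3, at 257 ± 88.5 against 82.9 ± 37.7, did not pass over all genes (adjusted p = 0.0830). Of 25 neutrophil identity genes, S100a8 rose and 16 rose adjusted over the list alone (median 0.77, adjusted p = 2.05e-14; adjusted p = 0.126 with an estimated correlation). Of 16 B cell markers, Cd74, Ebf1, Fcmr and H2-Eb1 fell and 12 fell adjusted over the list alone (median -2.78, or -2.91 with genes listed at 0 put at the floor; adjusted p = 4.68e-13; adjusted p = 0.141 with an estimated correlation). Of 17 monocyte markers, Ccr2 and Fn1 fell, and 7 fell and 1 rose adjusted over the list alone (median -1.73, adjusted p = 2.10e-06; adjusted p = 0.126 with an estimated correlation). Gelatinase granule genes had a median of 0.78, no member called over all genes and 5 of 8 rising adjusted over the list alone (adjusted p = 5.46e-07; adjusted p = 0.141 with an estimated correlation). Homing receptors had Cd24a rising and 6 adjusted over the list alone (median 0.45), phagocytic receptors had Tyrobp rising, and 6 rising and 1 falling adjusted over the list alone (0.40). Motility genes had Tmsb4x rising and Capg falling, and 4 rising and 1 falling adjusted over the list alone (0.34). Their tests passed (adjusted p from 1.26e-07 to 1.44e-05) and were lost with an estimated correlation (adjusted p from 0.141 to 0.220).

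Interferon genes (median 0.46), glucocorticoid genes (0.38, Nfkbia rising), erythroid genes (0.38), glycolysis genes (0.31) and NADPH oxidase subunits (0.21, Cybb falling from 457 ± 131 to 192 ± 78.8, adjusted p = 0.0306) had 2, 2, 0, 0 and 3 members rising adjusted over the list alone. Their list adjusted p ranged from 1.10e-05 to 0.0292, and from 0.141 to 0.493 with an estimated correlation. Immediate early genes did not move as a list (median 0.04, adjusted p = 0.715), although Egr1 and Klf4 fell by both adjustments, over all genes and adjusted over the list alone. The chaperone Hsp90b1 of the endoplasmic reticulum fell from 129 ± 46.9 to 29.0 ± 5.14 (-2.07, adjusted p = 0.00374) in a list that did not pass. The 11 lists without a call had adjusted p from 0.0542 to 0.968.

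The 75 calls became 23, 199 and 49 without WT ZT5 replicates 5, 8 and 9, and 19 and 28 without Cxcr2 replicates 4 and 5. With edgeR 17 were called, of which 9 were higher and 8 lower, and with DESeq2 318. Ccr2 alone among the 20 genes taken by the rule kept its call whichever library was left out (highest adjusted p 0.0453). Ccr2 lost its call with robust edgeR (0.142), limma-voom (0.203) and the B cell covariate (0.988). None of the 20 kept its call in every alternative other than the covariate, and 19 lost it with the covariate, which overlaps with this contrast too. The 19 other than Ccr2 lost theirs without at least 1 library (highest adjusted p per gene from 0.0626 to 0.470, reached without Cxcr2 replicate 4 or 5 for all but Itpr1).

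The comparison of Cxcr4 mutants with WT ZT5 asked what loss of the receptor that retains neutrophils in the bone marrow changes in the circulating cells. Specific granule genes, which neutrophils transcribe at the myelocyte stage, were far higher in the mutants. Lactoferrin (Ltf) rose from 31.1 ± 11.7 to 3626 ± 627 (log2 fold change 6.88, SE 0.47, adjusted p = 2.82e-10), the cathelicidin Camp from 17.4 ± 8.75 to 2182 ± 304 (7.03, SE 0.54, adjusted p = 1.93e-09) and Ngp from 45.2 ± 32.3 to 3969 ± 1484 (6.57, SE 0.49, adjusted p = 1.19e-09). The surface glycoprotein Cd177 rose from 88.5 ± 28.9 to 1531 ± 270.0 (4.13, SE 0.26, adjusted p = 5.27e-11), and the chitinase-like Chil3 by 4.55 (adjusted p = 0.000105). Immediate early genes fell, and so did the chemokine Cxcl2: Egr1 went from 918 ± 360 to 10.1 ± 10.9 (-6.89, SE 0.52, adjusted p = 1.43e-09) and Cxcl2 from 140 ± 138 to 3.86 ± 6.69 (-5.48, SE 0.90, adjusted p = 0.000225). The cholesterol genes Abca1 and Apoe fell by 5.14 (adjusted p = 6.60e-07) and 4.88 (adjusted p = 2.82e-10). The antigen presentation gene H2-Ab1 and the monocyte genes Adgre4 and Ccr2 changed by -5.49, -4.78 and -4.70. Adpgk, Sept5, Abca13, Anxa3 and Mcam rose by 4.97, 4.89, 4.79, 4.31 and 3.64, and Lrp1, Msi2 and Man1a changed by -4.61, -4.56 and -4.51. In total 456 genes were higher and 467 lower, and 2350 had an unadjusted p under 0.05. Of the 923, 891 had groups that did not overlap (2953 of all genes, 10% by chance). The balance of directions moved to 511 higher and 302 lower with limma-voom, 399 and 307 with robust edgeR, and 280 and 425 with an absolute log2 fold change over 1.

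Of 12 specific granule genes measured, 10 rose and none fell, over all genes and adjusted over the list alone (median 2.64, list adjusted p = 2.16e-23; adjusted p = 0.000533 with an estimated correlation). Besides those above, Lcn2 rose by 2.63 (adjusted p = 1.40e-07), Lyz2 by 1.58 (adjusted p = 1.42e-06) and Olfm4 by 2.65 (adjusted p = 0.00368), members named after their values were seen. Gelatinase granule genes rose too, 6 of 8 by both adjustments, over all genes and adjusted over the list alone (median 1.34, adjusted p = 5.04e-14; adjusted p = 0.0373 with an estimated correlation). They included the collagenase Mmp8, from 402 ± 142 to 3046 ± 463 (2.97, adjusted p = 2.80e-09), Retnlg (2.53, adjusted p = 1.93e-09), Itgam (1.28, adjusted p = 6.18e-05) and Mmp9 (1.26, adjusted p = 0.000103). Of 7 NADPH oxidase subunits 4 rose, and 6 adjusted over the list alone (median 0.81, adjusted p = 1.95e-08; adjusted p = 0.0334 with an estimated correlation), with Ncf1 at 1430 ± 199 against 402 ± 44.1 and Cybb at 1601 ± 137 against 457 ± 131. Azurophil granule genes, made earlier in the bone marrow, did not move as a list (5 measured, adjusted p = 0.267): Serpinb1a rose by 2.65 and Igsf6 by 0.68 while Ctsc fell by 3.25, each by both adjustments, over all genes and adjusted over the list alone. None of the 11 cell cycle genes measured was called by either adjustment (list adjusted p = 0.114). Mpo, Elane, Prtn3 and Ctsg were not analysed here.

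Immediate early genes fell as a list, 17 of 23 over all genes and 19 adjusted over the list alone (median -1.50, adjusted p = 1.73e-17; adjusted p = 0.0334 with an estimated correlation). Fosb went from 345 ± 52.2 to 33.7 ± 27.1 (-3.58, adjusted p = 3.95e-07), Fos from 2048 ± 456 to 524 ± 360 (-2.18, adjusted p = 4.10e-05) and Junb from 316 ± 13.5 to 112 ± 22.5 (-1.50, adjusted p = 2.34e-05). Of 27 NF-kB genes 6 fell and 1 rose, and 9 fell and 2 rose adjusted over the list alone (mean -0.97, adjusted p = 0.00124; adjusted p = 0.0619 with an estimated correlation). The cyclooxygenase Ptgs2 fell from 328 ± 57.3 to 17.7 ± 13.7 (-4.35, adjusted p = 2.07e-09) and Il1b from 2982 ± 501 to 1472 ± 178 (-1.01, adjusted p = 0.00118), whereas Il1rn rose by 1.35 (adjusted p = 0.000146). Interferon genes had 9 of 27 rising and 15 adjusted over the list alone, Cmpk2 first (2.50, adjusted p = 5.13e-07; median 0.94, list adjusted p = 2.90e-10; adjusted p = 0.125 with an estimated correlation). The mean interferon level stood at 6.65 and 6.59 in Cxcr4 replicates 2 and 5, but at 5.32 in replicate 4, within the 5.31 to 5.50 of WT ZT5. Motility genes had 13 of 30 rising and 19 adjusted over the list alone, including Arhgdib (1.39), Vcl (1.59) and Capg (2.12) (median 0.54, adjusted p = 2.86e-15; adjusted p = 0.0655 with an estimated correlation). Homing receptors went both ways, with 9 rising, among them Cd177, Cd24a and the formyl peptide receptor Fpr2 (1.69, adjusted p = 4.86e-06), and 3 falling, namely Cxcr4, Itgb1 and Pecam1. Among all members 11 rose and 5 fell adjusted over the list alone (median 0.23, adjusted p = 0.00154; adjusted p = 0.253 with an estimated correlation).

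The clock list did not pass (adjusted p = 0.0606), yet Per2 rose from 33.4 ± 10.2 to 211 ± 32.8 (2.66, adjusted p = 0.000134) while Per1 fell from 187 ± 18.0 to 78.2 ± 20.7 (-1.28, adjusted p = 0.000480) and Csnk1d by 0.80 (adjusted p = 0.00475); 1 rose and 5 fell adjusted over the list alone. The glucocorticoid list did not pass either (adjusted p = 0.650), with Anxa1 rising by 2.29 (adjusted p = 6.28e-09) and Per1, Nfkbia and Dusp1 falling. Erythroid genes had 11 of 18 falling and 14 adjusted over the list alone (median -2.38, or -2.51 with the gene listed at 0 put at the floor; adjusted p = 1.47e-16; adjusted p = 0.0555 with an estimated correlation), among them Slc4a1 (-3.95, adjusted p = 1.40e-05) and Alas2 (-2.84, adjusted p = 9.50e-06). B cell markers had 11 of 16 falling and 16 adjusted over the list alone (median -3.65, adjusted p = 6.89e-15; adjusted p = 0.0655 with an estimated correlation). Monocyte markers had 11 of 17 falling and 13 adjusted over the list alone (median -2.64, adjusted p = 2.61e-07; adjusted p = 0.0555 with an estimated correlation), but Ly6c2 rose from 34.3 ± 2.93 to 288 ± 28.4 (3.03, adjusted p = 4.71e-08). Neutrophil identity genes also split, with 11 of 25 rising and 4 falling, and 12 and 5 adjusted over the list alone (median 0.33, adjusted p = 0.000109; adjusted p = 0.253 with an estimated correlation). S100a8 rose from 1458 ± 453 to 5053 ± 1382 (adjusted p = 7.00e-06) and Ly6g, the sorting antigen, by 2.73 (adjusted p = 7.14e-05), while Ifitm1 fell by 3.10 (adjusted p = 6.79e-06). Glycolysis genes had 3 rising and 1 falling of 18, and 8 and 1 adjusted over the list alone (median 0.16, adjusted p = 0.00463; adjusted p = 0.253 with an estimated correlation). Heat shock genes had Hsp90b1 and Pdia4 falling by both adjustments, over all genes and adjusted over the list alone (median -0.39, adjusted p = 0.0488; adjusted p = 0.137 with an estimated correlation), and platelet genes had none called and 1 rising and 5 falling adjusted over the list alone (median -1.79, adjusted p = 0.0491; adjusted p = 0.570 with an estimated correlation).

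Among the lists not called, phagocytic receptors had 2 members rising and 5 falling, and 5 and 6 adjusted over the list alone (adjusted p = 0.870). Apoptosis genes had 2 rising and 3 falling, and 2 and 5 adjusted over the list alone (adjusted p = 0.363), with Bcl2l11 down by -1.26 (adjusted p = 0.00376). T and NK cell genes had Cd2 falling (adjusted p = 0.594 for the list) and eosinophil and basophil genes had Siglecf falling (adjusted p = 0.290), each the only member called adjusted over the list alone. Respiratory chain genes had none of 41 members called in any of the 5 comparisons, by either adjustment (adjusted p = 0.255 in this one). The 923 calls became 607 and 596 without Cxcr4 replicates 4 and 5. They became 137 with the mean level of B cell markers as a covariate, which overlaps with this contrast too. In that fit 9 of the 20 genes taken by the rule lost their call. All of the 20 genes taken by the rule kept it whichever library was left out (highest adjusted p 0.0179), although Cxcl2 lost it with robust edgeR, DESeq2 and limma-voom, Adgre4 with robust edgeR, and H2-Ab1 and Man1a with limma-voom.

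The comparison of Cxcr4 mutants with the libraries labelled Cxcr2-deficient asked how groups labelled as deficient in opposed receptors differ, and it shares no library with WT. Specific granule genes again separated them: Ltf was at 3626 ± 627 against 23.9 ± 19.8 (log2 fold change 7.44, SE 0.53, adjusted p = 1.08e-09), with Ngp (6.52, SE 0.54, adjusted p = 1.60e-08), Camp (6.48, SE 0.61, adjusted p = 1.17e-07) and Chil3 (6.13, SE 0.79, adjusted p = 1.28e-05). The actin-capping gene Capg and the scaffold gene Ahnak were higher in the Cxcr4 mutants by 4.06 (adjusted p = 5.75e-07) and 3.96 (adjusted p = 5.24e-08), as were Adpgk, Mcam and Serpinb1a by 5.42, 5.42 and 3.94. Cxcl2, Ptgs2 and Fosb were lower. Cxcl2 was at 3.86 ± 6.69 against 247 ± 75.1 (-6.70, SE 1.01, adjusted p = 0.000109), Ptgs2 at 17.7 ± 13.7 against 398 ± 59.8 (-4.64, SE 0.38, adjusted p = 1.34e-08) and Fosb at 33.7 ± 27.1 against 550 ± 132 (-4.24, SE 0.41, adjusted p = 2.11e-07). Cxcr1, which lies beside Cxcr2 on chromosome 1, was at 0.799 ± 1.38 against 45.8 ± 4.70 (-4.96, adjusted p = 0.000497), and Cxcr4 itself fell by 4.35 (adjusted p = 3.84e-10). The red cell anion exchanger Slc4a1, Piwil2, Wfdc17, Apol11b and Xkrx were lower, with changes of -5.16, -4.27, -4.16, -4.05 and -3.98. In total 257 genes were higher and 208 lower, and 1881 had an unadjusted p under 0.05. All 465 had groups that did not overlap (3764 of all genes, 20% by chance).

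Of 12 specific granule genes 9 were higher, and 9 higher and 1 lower adjusted over the list alone (median 3.09, list adjusted p = 1.23e-20; adjusted p = 0.000936 with an estimated correlation). Of 27 NF-kB genes 8 were lower and 12 adjusted over the list alone (median -0.79, adjusted p = 2.13e-10; adjusted p = 0.00429 with an estimated correlation), among them Nfkbia at 80.4 ± 12.4 against 530 ± 72.3 (-2.71, adjusted p = 5.20e-06), Nfkbiz (-1.73, adjusted p = 1.02e-05) and Il1b (-1.59, adjusted p = 2.65e-05). Of 23 immediate early genes 10 were lower and 17 adjusted over the list alone (median -1.44, adjusted p = 9.53e-20; adjusted p = 0.0237 with an estimated correlation), including Atf3 (-3.06, adjusted p = 6.67e-06) and Zfp36 (-1.73, adjusted p = 5.00e-06). Of 18 erythroid genes 12 were lower and 14 adjusted over the list alone (median -2.86, or -2.90 with the gene listed at 0 put at the floor; adjusted p = 5.11e-24; adjusted p = 0.0280 with an estimated correlation). B cell markers, by contrast, had none of 16 called by either adjustment (adjusted p = 0.0787), and monocyte markers had only Ly6c2 higher (2.28, adjusted p = 2.63e-05), with 1 higher and 2 lower adjusted over the list alone (list adjusted p = 0.347).

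Phagocytic receptors had 1 member higher and 5 lower, and 1 and 8 adjusted over the list alone (median -0.28), and glucocorticoid genes 1 and 4 by both adjustments, over all genes and adjusted over the list alone (median -0.66). Gelatinase granule genes had 3 higher, and 4 higher and 1 lower adjusted over the list alone (median 0.71), NADPH oxidase subunits 2 by both (median 0.35) and motility genes 3 by both (median 0.18). Interferon genes had Cmpk2 higher by both (median 0.46). Clock genes had Per2 higher (2.19, adjusted p = 0.00499) with Csnk1d and Per1 lower, by both (median -0.51). Platelet genes had Thbs1 higher by both, against a median of -1.65 (-1.76 with genes listed at 0 put at the floor). These 8 list tests passed (adjusted p from 2.50e-05 to 0.0476) and were lost with an estimated correlation (adjusted p from 0.154 to 0.602). Neutrophil identity genes had 5 higher and 8 lower, and 9 and 11 adjusted over the list alone (list adjusted p = 0.226), with the sorting antigen Ly6g at 213 ± 38.1 against 44.1 ± 24.7 (2.35, adjusted p = 0.00195). The 12 lists without a call had adjusted p from 0.0747 to 0.921. The 465 calls became 237 and 278 without Cxcr2 replicates 4 and 5, and DESeq2 called 707. All of the 20 genes taken by the rule kept their calls whichever library was left out (highest adjusted p 0.0363).

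Across comparisons, the question was whether the groups labelled as mutant at ZT5 resemble wild type at ZT13. Across 11255 genes, which are not independent replicates, the log2 fold changes of ZT13 minus ZT5 correlated with those of the libraries labelled Bmal1-deficient (Pearson r = 0.56), the libraries labelled Cxcr2-deficient (0.55) and the Cxcr4 mutants (0.50). Sharing a control gave 0.49, 0.43 and 0.48 in data simulated without group differences, so these correlations lay within 1 SD (0.196, 0.189 and 0.193) of that level. The covariances were 0.406, 0.444 and 0.428 against simulated 0.262, 0.253 and 0.245, more than 1 simulated SD (0.123, 0.131 and 0.121) above that level. The simulation shuffled the residuals of all 14 libraries over the groups, so it did not keep the spread of WT ZT5 itself. It therefore cannot say what these controls alone would give. Without a shared library, ZT13 minus ZT5 against Cxcr4 minus Cxcr2 gave r = -0.02 (simulated -0.01, SD 0.26). That contrast cancels any shift that both groups share, so it cannot tell whether they resemble ZT13. Called genes overlapped between these groups: 14 higher and 18 lower in both the Bmal1 and Cxcr2 comparisons, where independent lists would give 0.0981 and 0.313, a number that leaves out the shared controls. The Bmal1 and Cxcr4 comparisons shared 15 higher and 42 lower, and the Cxcr2 and Cxcr4 comparisons 9 higher and 32 lower. With the 9 genes called at ZT13 the overlaps were 0 higher and 2 lower for Bmal1, 0 and 3 for Cxcr2, and 2 and 2 for Cxcr4. Ahnak, Ccr2 and Lrp1 were examples of genes with the same control: Ccr2 and Lrp1 fell in all 3 groups compared with it, while Ahnak was at 68.1 and 70.4 in the Bmal1 and Cxcr2 groups and at 1115 in the Cxcr4 mutants. With 3 control libraries the controls could not be divided between comparisons. In the data simulated without group differences, the mean overlap was at most 0.01 genes per direction for each pair of groups labelled as mutant. Those data did not keep the spread of WT ZT5, so how much of the overlap comes from these controls stays open. The Cre that these groups share was not tested apart either.

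A time-of-day score was the mean log2 value of the 100 genes most clearly higher at ZT13 minus that of the 100 most clearly lower. Only 9 genes were called at ZT13, so most of the score genes had not passed. It was 1.30 ± 1.06 in WT ZT5 and 4.76 ± 0.33 in WT ZT13, the libraries that chose the genes and were therefore not tested. Across these libraries the score rose as the mean level of B cell markers fell. It went from 0.115 at a level of 7.58 (WT ZT5 replicate 5) to 5.07 at 2.14 (WT ZT13 replicate 2). Time of day and the content of other cells therefore cannot be told apart in it. The libraries labelled as mutant did not keep that order, with 3.83 at 2.07 (Cxcr4 replicate 5) and 4.08 at 3.08 (Cxcr2 replicate 5). The groups labelled as mutant, all taken at ZT5, scored 3.71 ± 0.13 (Bmal1), 3.98 ± 0.13 (labelled Cxcr2-deficient) and 3.84 ± 0.10 (Cxcr4). The score genes were picked for differing between these same WT ZT5 and WT ZT13 libraries. Any group measured apart from them therefore tends to score between them, above WT ZT5 and below WT ZT13. The distance of the groups labelled as mutant from either was not tested. These groups differed by -0.27 (Bmal1 minus Cxcr2, exact permutation p = 0.1), -0.13 (Bmal1 minus Cxcr4, exact permutation p = 0.4) and 0.14 (Cxcr2 minus Cxcr4, exact permutation p = 0.3). All were 2-sided, and 0.1 is the smallest p that 3 libraries against 2 or 3 allow. Each difference changed sign under an alternative, to 0.175 and 0.229 with only called genes of absolute log2 fold change over 1, and to -0.0329 with quantile normalization for Cxcr2 minus Cxcr4.

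**Figure D4:**
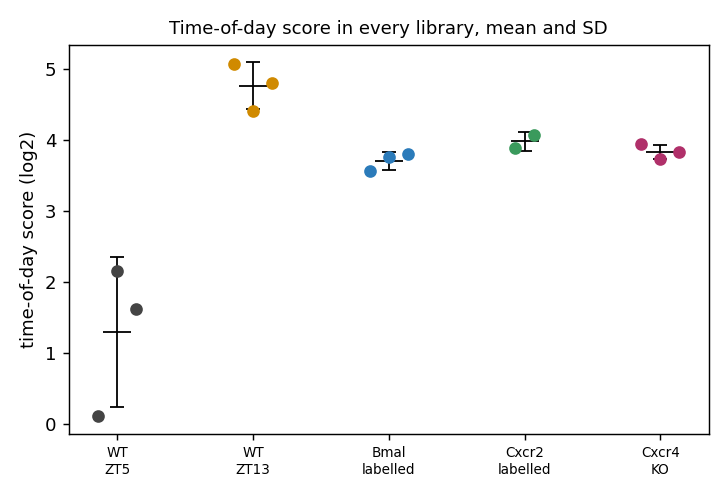
Time-of-day score (log2 units) of each library (points) in the 5 groups, with mean and SD (bars). The 8 libraries labelled as mutant lay between WT ZT5 (1.30 ± 1.06) and WT ZT13 (4.76 ± 0.33), a place that the choice of the score genes favours.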

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

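The tests with edgeR TMM scaling and with B cell markers as a covariate were chosen only after the data were seen. Of 90 named-gene results 27 kept their call under every alternative and none reversed. List tests were not run with edgeR, DESeq2, limma-voom or 2 groups only. Of 62 called lists 8 kept their call under every alternative run for lists. These were specific granule, gelatinase granule, NADPH oxidase and immediate early genes in the Cxcr4 comparison, and specific granule, NF-kB, immediate early and erythroid genes in Cxcr4 against Cxcr2. The correlations between comparisons changed by less than 1 simulated SD in every alternative run for them. That SD was wide (0.189 to 0.256), so this says little about their stability. They were not run with array weights, the replicate block, the B cell covariate or 2 groups only. DESeq2 tests, limma-voom and the planned edgeR forms were not run for them either. For the other values below the cause was not tested, except that fits without a library or with 2 groups have fewer samples, and that the B cell covariate is highest in WT ZT5 and so overlaps with the contrasts by construction.

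For WT ZT13 the 9 called genes became 36 with array weights, 3 with edgeR (TMM, RLE or robust), 88 with DESeq2, 15 with limma-voom, 3 with 2 groups only, 1 with the B cell covariate and 4 with the replicate block; leaving out a library gave 4, 102 and 7 (WT ZT5 replicates 5, 8, 9) and 2, 10 and 2 (WT ZT13 replicates 2, 8, 9). For Bmal1 the 115 became 62 with pseudocount 0.1, 36, 34 and 39 with edgeR TMM, RLE and robust, 264 with DESeq2, 40 with 2 groups only and 4 with the covariate; leaving out a library gave 23, 190 and 95 (WT ZT5) and 68, 28 and 26 (Bmal1 replicates 2, 3, 4). For Cxcr2 the 75 became 41 with pseudocount 0.1, 17, 16 and 12 with edgeR TMM, RLE and robust, 318 with DESeq2, 40 with limma-voom, 12 with 2 groups only and 1 with the covariate; leaving out a library gave 23, 199 and 49 (WT ZT5) and 19 and 28 (Cxcr2 replicates 4, 5), where the lone sample left is assumed to vary like the other groups. For Cxcr4 the 923 became 1432 with array weights and 137 with the covariate, and 627, 945 and 674 (WT ZT5) or 691, 607 and 596 (Cxcr4 replicates 2, 4, 5) without a library. Cxcr4 against Cxcr2 went from 465 to 707 with DESeq2, and to 237, 278, 386, 322 and 325 without Cxcr2 replicates 4 and 5 and Cxcr4 replicates 2, 4 and 5. The change of Cxcr2 in its own group became -0.66 with quantile normalization (adjusted p = 0.0463).

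For list tests, WT ZT13 went from 11 to 5 with quantile normalization, 2 with the covariate, 4 with the replicate block, 0 with an estimated correlation, 0 with fry and 6 without WT ZT5 replicate 5. Bmal1 went from 11 to 5 with quantile normalization, 7 with array weights, 2 with the covariate, 0 with an estimated correlation and 1 with fry. Cxcr2 went from 13 to 8, 2, 0 and 2 with quantile normalization, covariate, estimated correlation and fry. Cxcr4 went from 15 to 4 and Cxcr4 against Cxcr2 from 12 to 4 with an estimated correlation. Lists that reversed did not pass: under quantile normalization, motility in WT ZT13 (adjusted p = 0.127) and phagocytosis in Bmal1 (0.943). Under the covariate these were, in WT ZT13, gelatinase granule (0.912), glycolysis, motility and neutrophil (0.534 each), homing (0.385) and phagocytosis (0.749); in Bmal1, gelatinase granule (0.738), glycolysis (0.954), homing (0.799) and phagocytosis (0.322); in Cxcr4, glycolysis (0.862), homing and neutrophil (0.721 each).

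The score difference Bmal1 minus Cxcr2 was 0.175 with only called genes of absolute log2 fold change over 1, and -0.421 to -0.176 without a library. Bmal1 minus Cxcr4 was 0.229 with called genes, 0.140 with pseudocount 0.1, -0.287 with quantile normalization and -0.383 to -0.0305 without a library. Cxcr2 minus Cxcr4 was 0.369, -0.0329 and 0.0254 to 0.239 with pseudocount 0.1, quantile normalization and without a library.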

Other observations

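Tests of the region around Arntl, of B cell marker levels and of neutrophil genes in the Cxcr4 mutants were chosen only after the results were seen; the tests on scaling, family neighbours and other splits were written first, but edgeR TMM, 1 of the scalings used, was chosen after the data were seen.

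Cxcr1 was at 45.8 ± 4.70 in the libraries labelled Cxcr2-deficient, against 7.65 ± 4.99 in WT ZT5 (limma adjusted p = 0.131) and 0.799 ± 1.38 in the Cxcr4 mutants. Erythroid genes summed to 8916 ± 5141 in the Cxcr4 mutants and 49164 ± 24284 in WT ZT5.

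Called genes of the Bmal1 comparison were concentrated near Arntl, 3.89 times the share of tested genes there. A strain variant carried along with the targeted locus would give this, although the calls of Spn and Hbb-bt there need not come from the locus. Near Arntl lay 11 of 115 calls, 5 of 36 with edgeR TMM, 9 of 23 without WT ZT5 replicate 5, 2 of 4 with the B cell covariate and 16 of 264 with DESeq2. Shared reads with a family member could add to it. Of these genes, 72.7% (8 of 11) had a gene within 1 Mb whose symbol began with the same letters. Shared letters, such as Gm for predicted genes, do not show that reads can be shared, so this share does not decide. An effect of the mutation itself was not excluded.

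B cell markers were highest in WT ZT5 for 100% of the 16 measured. This restates the pattern and does not test whether B cells were carried along, which sorting on Ly6G would remove, so their source stays open. If all other cell types rose alike as neutrophils fell, their markers would move together. They moved apart at ZT13: B cell -2.60, monocyte -1.04, T and NK cell -0.32 (SE 0.38), platelet 0.10 (SE 0.13) and erythroid 0.56 (SE 0.10, errors over genes). This argues only against an equal rise, and the erythroid list no longer passed without WT ZT5 replicate 5. A lower share of neutrophils with a rise of only some other cells is not excluded. Neutrophil genes summed to 16066.5, 27350.7 and 24513.9 in WT ZT5 replicates 5, 8 and 9, and B cell markers to 4267, 540 and 1170. Replicate 5 alone does not account for the B cell difference at ZT13, since 63.3% of its log2 size stayed without that library.

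In the Cxcr4 mutants specific granule genes were higher and immediate early genes lower. The choice among 3 scalings mattered little, as the smaller of the list medians was at least 1.49 in size under each. They shifted the median gene by only 0.144 (quantile), -0.0224 (DESeq2 size factors) and 0.0140 (edgeR TMM). The check could therefore hardly have failed, and it does not exclude other errors of scaling. Fewer other cells may be part of it, but specific granule genes exceeded neutrophil identity genes by 2.30 (SE 0.80 over genes). Immediate early genes were also lower than in the libraries labelled Cxcr2-deficient (-1.44, SE 0.24 over genes). Genes of a list are not independent, and these errors do not measure the spread between libraries. Release of younger cells, handling and length bias were not tested.

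Among 10 splits of the samples, which are too few for a share under 0.05, the real one called 9 genes for WT ZT13 (highest other 4), 115 for Bmal1 (highest other 1) and 923 for Cxcr4 (highest other 0). For lists it called 11 (highest other 13), 11 (highest other 11) and 15 (highest other 12). The splits with at least as many calls, the real one included, numbered 1, 1 and 1 for genes and 5, 4 and 1 for lists.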
